A study of Mus musculus with 3 samples.

How the data were processed

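Messenger RNA was profiled in 3 libraries from primary mouse bone marrow-derived dendritic cells. Per the labels' protocols, bone marrow from femurs and tibias was freed of red cells and grown with granulocyte-macrophage colony-stimulating factor (GM-CSF), and the floating cells were moved to new plates every other day to limit macrophages. The non-adherent cells were collected on day 6 and then cultured for 48 h without addition (control), with buffer, or with 800 ng/ml of recombinant articulatin B chain (rATB). The dose label of the buffer library reads 1 ng/ml, and its meaning is unclear, so no dose was assigned to the buffer. Per the labels' protocols, total RNA was extracted with TRIzol, RNA integrity was examined, and libraries were made with a TruSeq RNA version 2 kit and read as 150-bp pairs on a HiSeq2500. That kit does not mark strand, so reads from a gene and from an overlapping antisense gene cannot be told apart.

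Per the submitters' processing notes, reads were aligned with TopHat2 2.0.13, and the notes name the build GRCh37. That is the name of a human build, while the deposited gene identifiers are mouse Ensembl identifiers, so the build that was used is unclear and no coordinates are given. The read counter, the annotation release and the scaling method are not given in the sources used here. The deposited table held 37991 gene rows with an identifier, a symbol, a description and 3 columns of log2 values, 1 per library, per the file headers. Cells with a spreadsheet error stood for the log2 of 0 and made up 53.3% of the control column, 53.1% of the buffer column and 54.0% of the rATB column. On the linear scale, 100% of the deposited values above 0 in each column were whole multiples of the smallest value, within a tolerance of 1e-06. The authors' deposited log2 values were therefore read as log2 of a read count multiplied by a scaling factor shared by the whole column. That factor was 1 for the control, 1.04 for the buffer library and 1.13 for the rATB library.

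Read counts recovered in this way summed to 17776492 for the control, 16105080 for the buffer library and 15203139 for the rATB library. Values are in scaled reads per 1000000, called units: the count with the deposited scaling kept, times 1000000 and divided by the total reads of the control library. A value of 1 unit corresponded to 17.8 reads in the control, 17.1 in the buffer library and 15.7 in the rATB library. A count of 0 allowed a level of up to 0.169, 0.176 and 0.191 units in the same order, which is the level of 3 counts. Exact conditional (Clopper-Pearson) 95% intervals were computed for ratios of 2 libraries from their counts. These intervals and limits cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules.

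Symbols damaged by a spreadsheet, 25 in number, were restored from the gene identifiers with a table of current names, which held 32919 of the 37991 identifiers. Rows sharing a symbol were summed, which left 34590 symbols. Genes with a mean of at least 1 unit over the 3 libraries were kept, and 12559 passed. A gene was called higher or lower where log2(value + 1) differed by at least 1, a 2-fold change on that scale, which understates the change of low genes. The same rule was applied to each pair of libraries and to each library against both others. With 1 library per group there is no replicate check of any difference, no test of the treatment was possible, and no p-value is given. The planned rule assumed normalised values or raw counts, and the deposited file held log2 of scaled counts. The planned filter and size were kept on the unit above, with the deposited scaling in place of a scaling computed afresh.

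Before the data were examined, 25 gene lists and 10 lists of cell type markers were fixed. Of their 595 symbols, 593 were found in the table, 12 of them under an older symbol. For each list with at least 5 members past the filter, the median difference was set against 10000 random lists of the same size, drawn from 20 bins of mean expression. A list is said to stand apart for a library where its median lay outside the middle 95% of random lists, in the same direction, against both other libraries. The genes of a list are regulated together, so random lists of unrelated genes vary less than real lists would between cultures. The percentiles describe these libraries and are no test. The numbers of lists that stood apart for the buffer and control libraries serve as the reference.

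The genes named in the text were also fixed by rule before the data were examined. They were the 10 largest rises and 10 largest falls in the rATB library among named genes with a mean of at least 5 units, ranked by the smaller of its differences from buffer and control. To these came up to 4 members of each list by the same measure, 16 genes of dendritic cell function, and the 5 largest rises and falls of buffer against control. Any other named gene is marked as chosen after its values were seen. Gene symbols are those of the deposited table, so that Emr1 and Emr4 stand for Adgre1 and Adgre4, and Siglec5 for Siglecf.

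The calling rule was tested on simulated counts for 12549 genes. They were drawn from the counts of the control library, with sizes near those of the 3 libraries. The coefficient of variation between libraries was set at 0.1. For the rATB library against both others, it called 0 of 48 genes changed 1.5-fold, 33 of 49 changed 2.5-fold, 47 of 50 changed 4-fold and 50 of 50 changed 8-fold. It called 0 of 12352 unchanged genes, which follows largely from the chosen coefficient and does not give the rate between real cultures. Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, a filter at a mean of 5 units, median-of-ratios scaling, upper-quartile scaling, the highest row for each symbol, random lists not matched on expression, and lists without members shared with another list. Scaling by library totals was added after seeing the data. GC content and transcript length came from the GENCODE transcripts of mouse build GRCm38, the longest transcript of each identifier, and covered 97.7% of the genes past the filter. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.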

Results

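The messenger RNA of mouse bone marrow-derived dendritic cells was compared after 48 h without addition, with buffer, or with 800 ng/ml of recombinant articulatin B chain (rATB). Articulatin is a mistletoe protein with an enzymatic chain that inactivates ribosomes and a B chain. Bone marrow-derived dendritic cells are antigen-presenting cells grown from marrow with GM-CSF. Each of the 3 groups was a single library, of 17776492 reads for the control, 16105080 for buffer and 15203139 for rATB. The libraries were alike in make-up: the 10 most abundant genes took 12.4%, 11.9% and 12.1% of the reads in the same order, and mitochondrial genes took 2.07%, 2.27% and 1.95%. Values are scaled reads per 1000000 reads of the control library, called units, and each ratio is followed by its exact 95% interval for counting error. No group had a replicate, so every difference below is between libraries, with no check of the spread between cultures.

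The question of the series was how rATB changes the mRNA profile of these cells. The largest rise was that of Enpp2 (ENSMUSG00000022425), which encodes autotaxin, the enzyme that makes lysophosphatidic acid. It stood at 38.3 units with rATB, 0.703 with buffer and 1.18 in the control, 54.5 times the buffer level (interval 30.9 to 106). Lcn2 (ENSMUSG00000026822), a secreted binder of bacterial siderophores, reached 71.2 units against 10.4 and 11.9, a ratio to buffer of 6.84 (interval 5.83 to 8.05). The chemokine gene Ccl5 (ENSMUSG00000035042) was among the more abundant of these, at 1062 units with rATB, 200.1 with buffer and 171 in the control. Its ratio to buffer was 5.31 (interval 5.11 to 5.51). Cd72, a lectin-like surface receptor best known in B cells, stood at 13.3 units against 1.70 with buffer, and Itm2a at 15.7 against 2.63. Next came Slamf1, a co-stimulatory receptor, at 26.2 units against 6.44 with buffer, and Sphk1, a sphingosine kinase, at 55.2 against 12.7. Ppbp, a chemokine precursor, stood at 687 units against 207 with buffer. Slc1a2, a glutamate transporter, and Syt7, a synaptotagmin, completed the 10 largest rises with ratios to buffer of 3.65 (interval 2.81 to 4.80) and 3.66 (interval 2.81 to 4.82).

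Among the genes that were lower with rATB, Ear2 (ENSMUSG00000072596), an eosinophil-associated ribonuclease, stood at 2.92 units against 30.6 with buffer and 39.8 in the control. Reads of Ear2 can be shared with close copies of its family, so its level is uncertain. Asgr2 (ENSMUSG00000040963), a subunit of the asialoglycoprotein receptor, was at 20.9 units with rATB against 101.8 and 140.6, and the buffer level was 4.87 times the rATB level (interval 4.32 to 5.49). Tfrc (ENSMUSG00000022797), the transferrin receptor for iron uptake, was at 41.7 units against 198 and 189.6, a ratio of buffer to rATB of 4.75 (interval 4.37 to 5.17). Emr4, an adhesion receptor of myeloid cells, was at 28.4 units against 119.6 with buffer. The transcription factor gene Ehf stood at 5.66 units against 22.9 with buffer, and Il1rl1, the interleukin-33 receptor, at 2.92 against 12.5. The last of the 10 largest falls were Hr, Cldn1, Klk1b11 and Rnase6, whose buffer levels were 3.53, 3.84, 3.15 and 3.49 times the rATB levels. Klk1b11 belongs to a kallikrein family of near-identical genes, and its 304 units against 959 with buffer carry the same doubt as those of Ear2.

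By the fixed rule of a difference of at least 1 in log2(value + 1), 113 of the 12559 genes were higher in the rATB library than in buffer and 84 were lower. Against the control, 119 were higher and 111 lower. Of these, 78 were higher and 70 lower than in both other libraries. The buffer library stood apart from both others in 0 genes upward and 4 downward, and the control library in 1 upward and 0 downward. Since both comparisons share the rATB library, an unchanged library was simulated in its place in 100 draws, and it stood apart in a median of 3 genes and at most 6. Its noise was resampled from the buffer minus control differences of this single pair. The draws therefore cannot show how far a further untreated culture would lie. Independent lists of these sizes would have shared 1.07 higher and 0.742 lower genes. The lists are not independent, since they share the rATB library and buffer lay close to the control. A large overlap is therefore built into the comparison and is no evidence for a treatment effect. The standard deviation of the differences over all genes was 0.32 for rATB minus buffer, 0.33 for rATB minus control and 0.19 for buffer minus control. With a pseudocount of 0.1 the counts against buffer became 183 higher and 175 lower, and with a filter at 5 units 75 higher genes were left.

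**Figure D1:**
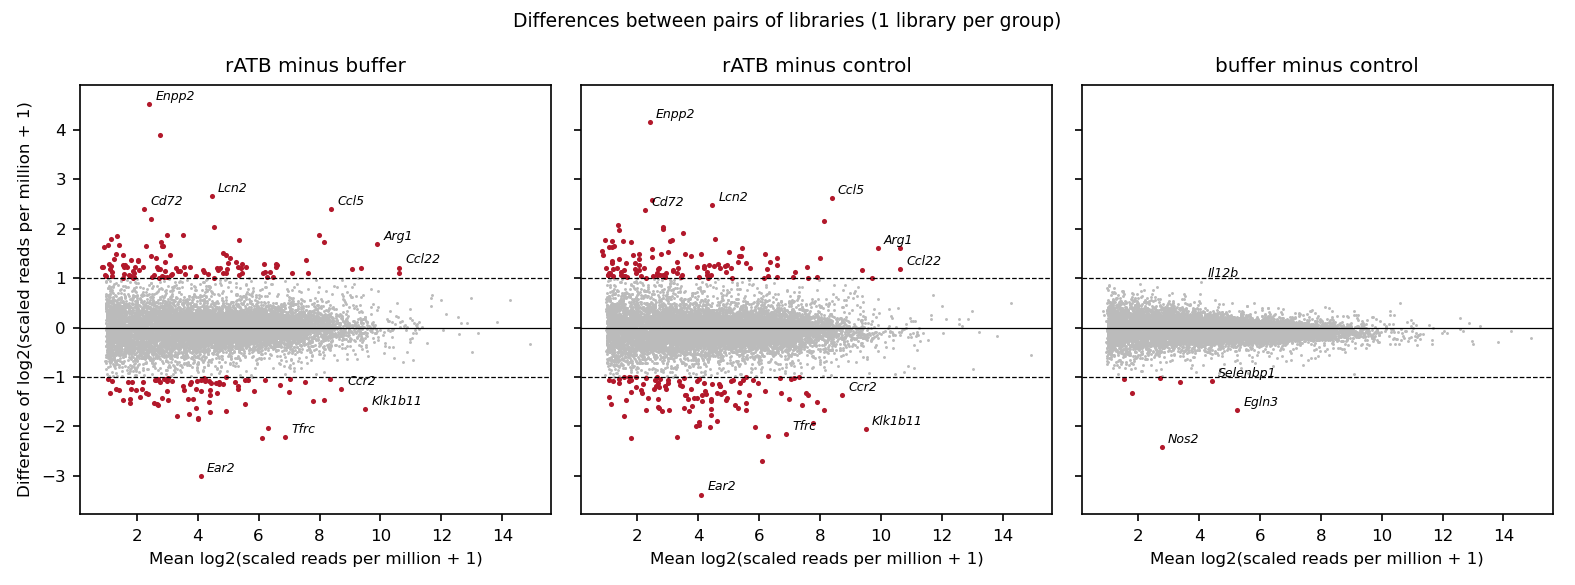
Each point is a gene past the filter, placed by its mean log2(value + 1) over the 3 libraries (horizontal) and by the difference of log2(value + 1) between the libraries named above each panel (vertical), where values are scaled reads per 1000000 reads of the control library. Red points differ by at least 1 (dashed lines): 113 higher and 84 lower for rATB minus buffer, 119 and 111 for rATB minus control, and 0 and 7 for buffer minus control.

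Genes of dendritic cell maturation and co-stimulation were on the whole higher with rATB. The list had a median difference of 0.23 from buffer and 0.22 from the control over 22 measured members, above the middle 95% of random lists in both comparisons. Of the 22, 13 were higher than in both other libraries and 7 lower, and the counting intervals excluded 1 against both for 10 and 5. Over all 12559 genes past the filter, the rATB library held the highest value in 33.2% and the lowest in 44.1%. Those shares are the reference for the members counted above or below both other libraries in each list. Slamf1 and Ccl22 were the members past the fixed rule against both other libraries. Ccl22, a chemokine that draws T cells, was at 2746 units with rATB against 1182 with buffer and 1204 in the control. Tnfrsf9, a co-stimulatory receptor, stood at 874 units against 384 with buffer (ratio 2.28, interval 2.21 to 2.35), and Cd200 at 48.1 against 24.2. The ligand genes for T cell co-stimulation Cd86 and Cd80 were at 374 and 110.2 units with rATB, against 192 and 67.8 with buffer and 183 and 66.8 in the control. Ccr7, the receptor that guides dendritic cells to lymph nodes, was at 1252 units against 723 and 621, and Cd83 at 322 against 222 and 188. Cd40 did not differ beyond counting error, at 19.8 units against 16.9 with buffer (ratio 1.17, interval 0.995 to 1.38). For this list the control library also stood apart, on the low side, since buffer minus control had a median of 0.03, above the middle 95% of random lists.

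Inhibitory and regulatory genes were higher as well, with medians of 0.19 against buffer and 0.11 against the control. Of 19 measured members, 11 were higher than in both other libraries and 5 lower. Arg1, the arginase of alternatively activated myeloid cells, was at 2029 units with rATB against 626 with buffer and 663 in the control, a ratio to buffer of 3.24 (interval 3.17 to 3.32). Socs3 and Socs1, which restrain cytokine signalling, stood at 223 and 94.5 units against 103 and 54.8 with buffer. Cd274, which encodes PD-L1, was at 781 units against 625 with buffer, and Havcr2 at 8.26 against 5.62. Arg1 and Socs3 were the members past the fixed rule against both other libraries. The list no longer stood apart when members shared with other lists were left out, and the smaller of its medians was then 0.00.

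Class II antigen presentation genes were lower with rATB, although none was lower than in both other libraries by the fixed rule. The median was -0.44 against buffer and -0.72 against the control over 13 members, below the middle 95% of random lists both times. Of the 13, 10 were lower than in both other libraries by more than counting error. Ciita, the master regulator of class II transcription, was at 106 units against 171 with buffer and 214 in the control, and the buffer level was 1.61 times the rATB level (interval 1.52 to 1.71). H2-Ab1 and H2-Eb1, which encode class II beta chains, were at 543 and 977 units against 811 and 1497 with buffer and 1031 and 1873 in the control. The peptide-loading gene H2-DMb1 was at 47.5 units against 69.5 and 86.0. The member higher than in both was Ctss, a cathepsin that acts in class II processing and was chosen after its values were seen, at 5150.4 units with rATB against 3481 with buffer. Buffer was also below the control over this list, at a median of -0.30, so the control library stood apart on the high side. The macrophage genes C1qa and C1qb were likewise highest in the control and lowest with rATB. Class I presentation genes had medians of 0.11 against buffer and 0.09 against the control over 14 members, inside the middle 95% of random lists against buffer. H2-K1, H2-D1 and B2m were at 371, 1449 and 1845 units with rATB against 281, 1151 and 1302 with buffer.

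**Figure D2:**
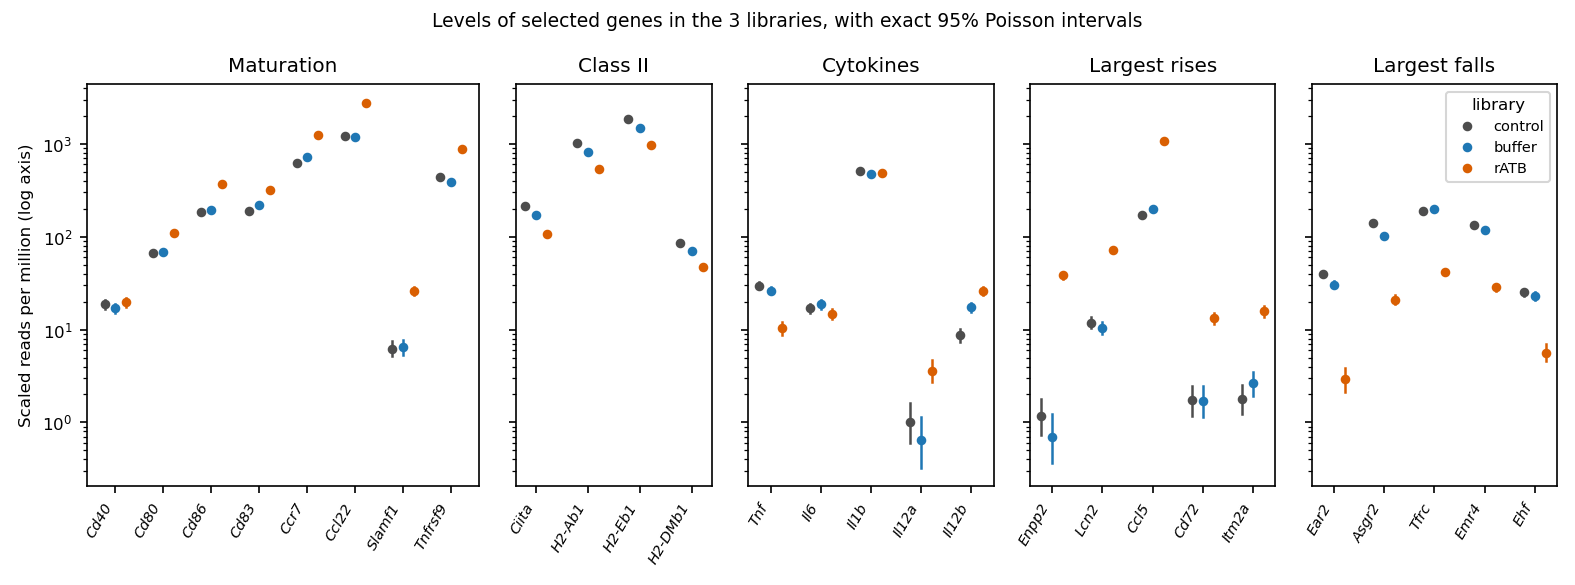
Levels of selected genes in scaled reads per 1000000 reads of the control library (log axis) for the control (grey), buffer (blue) and rATB (orange) libraries, 1 point per library with its exact 95% Poisson interval, which covers counting error only. Cd86 stood at 374 units with rATB against 192 with buffer, and Ciita at 106 against 171.

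Cytokine genes moved in both directions. The inflammatory cytokine list had medians of 0.30 against buffer and 0.21 against the control, with 12 of 19 members higher than in both other libraries and 5 lower. Il12a and Il12b, the subunits of interleukin-12, were at 3.62 and 26.1 units with rATB, against 0.644 and 17.4 with buffer and 1.01 and 8.66 in the control. Inhba and Il33 were at 15.3 and 2.16 units against 7.96 and 0.820 with buffer. Tnf was the member lower by the fixed rule, at 10.3 units against 26.3 and 29.8, and the buffer level was 2.55 times the rATB level (interval 2.13 to 3.08). Il1b did not differ beyond counting error from buffer (491 against 477 units), and Il6 stood at 14.7 units against 18.8. Il10 had 0 reads with rATB, which allows a level of up to 0.191 units, and 1 and 4 reads in the control and buffer libraries. The list lost its place above random lists with a filter at 5 units, where the smaller of its medians was 0.077.

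The chemokine list did not stand apart, with medians of -0.04 and 0.06 over 15 members, 7 of them higher and 7 lower than in both other libraries. By the fixed rule against both other libraries, Ccl5 and Ccl22 were the higher members and Cxcl10 the lower member. Cxcl10 rested on 3 reads with rATB against 25 with buffer and 38 in the control, a ratio of buffer to rATB of 7.68 (interval 2.34 to 39.7). Cxcl1 was at 12.3 units against 27.3 with buffer. Targets of the transcription factor NF-kB had medians of -0.05 and -0.14 over 26 members. Of these, 6 were higher and 17 lower than in both other libraries, 5 and 12 of them by more than counting error. In that list Nos2, the inducible nitric oxide synthase, was at 22.7 units with rATB, 0.586 with buffer and 7.48 in the control, while Nfkbiz and Cxcl2 were at 23.7 and 96.2 units against 41.5 and 177 with buffer. The medians of type I interferon-stimulated genes were 0.08 and -0.04 over 30 members, and those of interferon-gamma response genes 0.12 and 0.00 over 16. Within the first list Ifit2 was at 3.69 units against 7.96 with buffer, and Oasl1 at 12.8 against 6.85.

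Most but not all receptors of the uptake list were lower with rATB. The list of C-type lectins and uptake receptors had medians of -0.43 against buffer and -0.32 against the control, with 18 of 27 members lower than in both other libraries and 8 higher. Of the 18, 6 were lower than in both by the fixed rule. Of 20 macrophage and monocyte markers, 7 were lower and 1 was higher than in both other libraries by over 2 standard deviations. Those deviations are of the buffer minus control differences at the level of each marker, which over all genes spread less than the rATB differences. The share of all genes past that size was not computed. The list did not stand apart for rATB, with medians of -0.01 against buffer and -0.27 against the control. Mgl2 and Cd209a, lectins of dendritic cells and macrophages, were at 98.5 and 8.20 units against 278 and 25.0 with buffer and 381 and 36.2 in the control. Clec12a was at 13.6 units against 46.0 with buffer, a ratio of buffer to rATB of 3.38 (interval 2.90 to 3.95). Timd4, a receptor for dying cells, rested on 2 reads with rATB against 31 with buffer (ratio 14.3, interval 3.63 to 123). Lectin genes of the Clec4 cluster are close copies of each other, so their single values are less certain.

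Immediate-early, cell cycle and cholesterol genes were lower with rATB too. Immediate-early genes had a median of -0.36 in both comparisons, and 15 of 18 members were lower than in both other libraries by more than counting error. Myc and Nr4a1 were the members past the fixed rule against both other libraries, at 8.52 and 2.61 units, and the buffer levels were 2.23 (interval 1.82 to 2.75) and 2.49 (interval 1.73 to 3.66) times these. Egr2 was at 204 units against 419.9 with buffer, and Klf2 at 15.2 against 29.4. Cell cycle genes had medians of -0.45 and -0.33, with 23 of 26 members lower than in both other libraries and 15 beyond counting error. Cdc20, Plk1, Birc5 and Tk1 were at 8.20, 6.61, 10.3 and 18.8 units against 14.6, 13.2, 18.8 and 33.2 with buffer. The buffer library stood apart on the high side of this list, with a median of 0.15 over the control. Cholesterol biosynthesis genes had medians of -0.38 and -0.51, and 18 of 20 members were lower than in both other libraries. The control library also stood apart on the high side of this list, with buffer minus control at a median of -0.15. Lss, an enzyme of the pathway, was at 23.4 units against 34.4 with buffer, and Hsd17b7 was at 10.7 against 15.8. Pmvk was the member higher than in both, at 57.5 units against 36.5. No member of the cell cycle or cholesterol lists was past the fixed rule.

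The list of matrix metalloproteases and their inhibitors had small medians of 0.13 and 0.07 over 17 members, and it ceased to stand apart under 5 of the alternatives tried. Mmp19 and Timp1 were at 520.2 and 35.0 units with rATB against 290.4 and 21.4 with buffer. Mmp27 and Adamdec1 were low, at 4.32 and 2.22 units. Migration and adhesion genes had medians of 0.08 and 0.01 over 18 members. S1pr3, a sphingosine phosphate receptor, was at 16.5 units against 3.81 with buffer, while Ccr2 and Cx3cr1, receptors of monocytes, were at 229 and 2.10 against 544 and 8.20. The other gene lists did not stand apart for rATB, and the marker lists are given below. Their medians against buffer and control were -0.17 and -0.07 for oxidative burst and nitric oxide genes, -0.12 and -0.20 for inflammasome genes, and -0.02 and -0.18 for Toll-like receptor signalling. They were 0.04 and -0.12 for unfolded protein and stress response genes, 0.04 and -0.14 for lipid efflux and handling, and -0.06 and -0.08 for apoptosis and p53 targets. Galectins and other lectins had medians of -0.05 and -0.05, large-subunit ribosomal proteins -0.06 and -0.11, and housekeeping genes -0.01 and -0.08. Tlr4 was at 119 units with rATB and 121 with buffer, and Tlr2 at 265 against 304. Ddit4, a stress-response gene, was at 43.5 units against 19.7 with buffer, but 0 members of its list were higher than in the control by the fixed rule. Pparg and Fasn, genes of lipid metabolism, were at 4.00 and 84.3 units against 9.13 and 148 with buffer.

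**Figure D3:**
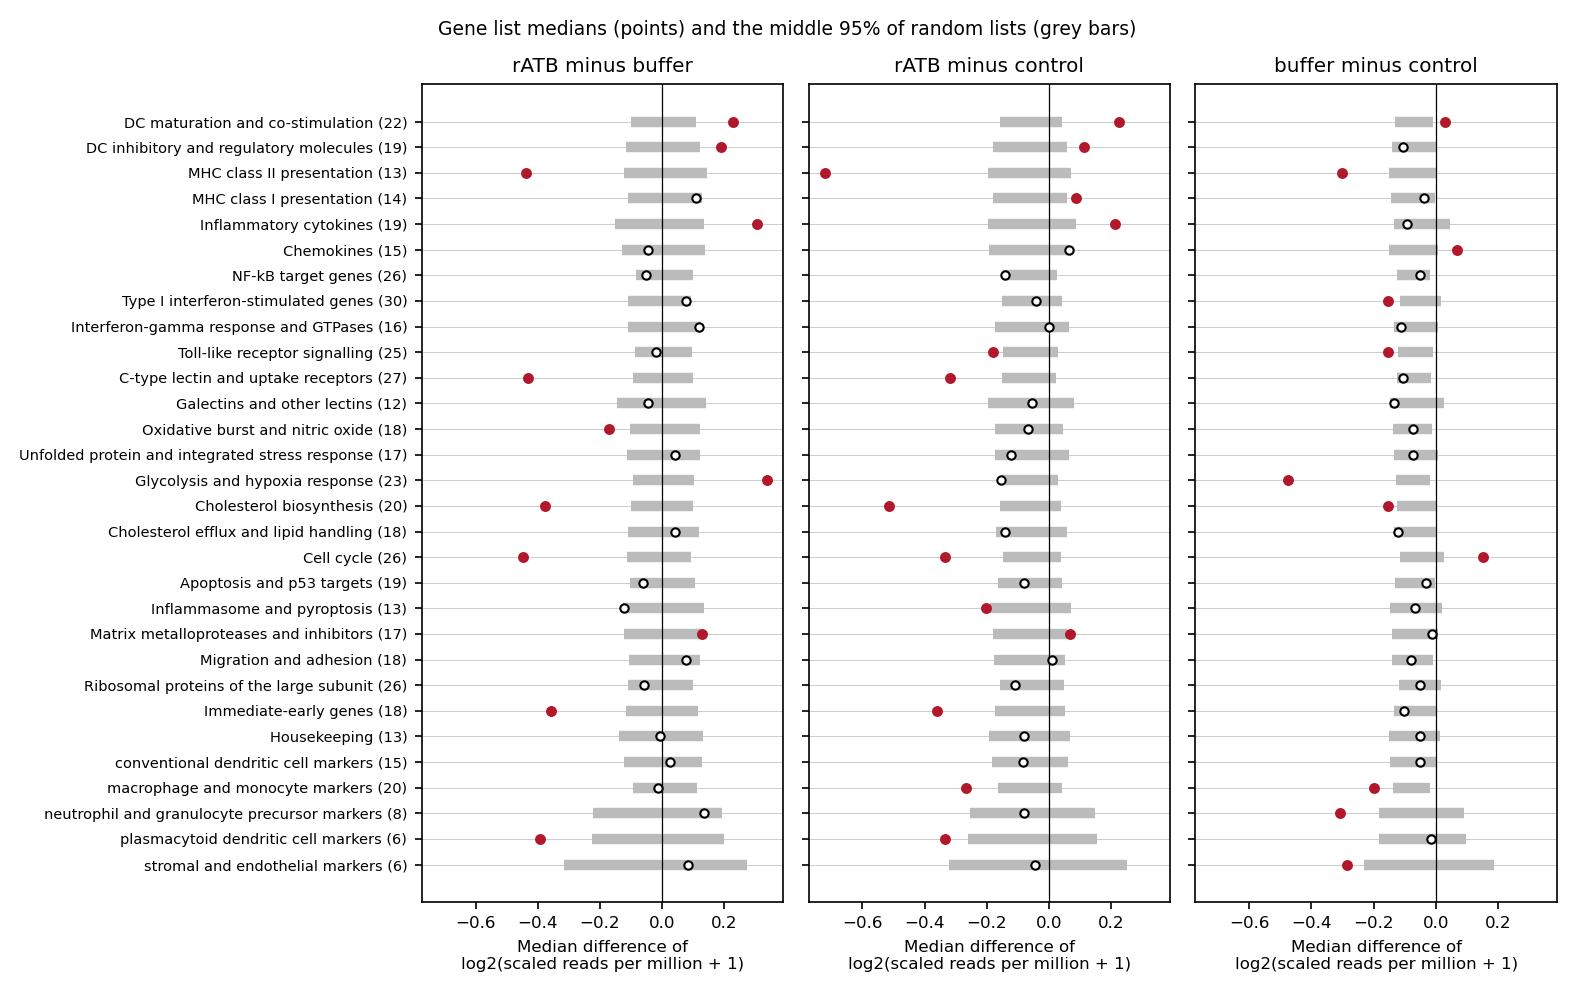
Median difference of log2(value + 1) over the measured members of each list (number in brackets) for the pair of libraries named above each panel, with the middle 95% of 10000 random lists of the same size and expression as grey bars. Red points lie outside that range; class II presentation lies at -0.44, -0.72 and -0.30 from left to right.

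Markers of cell types were followed in the same libraries. Conventional dendritic cell markers had medians of 0.03 against buffer and -0.08 against the control over 15 members. Itgax, the gene of CD11c, was at 981 units with rATB against 1213 with buffer, Flt3 and Irf8 were at 12.8 and 566 against 7.20 and 378, and Dpp4 was at 69.5 against 116. Macrophage and monocyte markers had medians of -0.01 and -0.27 over 20 members. The control library stood apart on the high side of this list, with buffer minus control at a median of -0.20. Retnla, Ccr2, C1qa and C1qb were at 136, 229, 134 and 96.9 units with rATB against 377, 544, 258 and 170.4 with buffer, while Emr1, the F4/80 gene, was at 432 against 456. Plasmacytoid dendritic cell markers had medians of -0.39 and -0.34 over 6 members, a result lost without the filter and with a filter at 5 units. Spib of that list was at 14.2 units against 32.4 with buffer, and Bst2 at 159 against 129. Neutrophil markers had medians of 0.14 and -0.08 over 8 members, with Lcn2 as the member past the fixed rule against both other libraries, and stromal and endothelial markers 0.08 and -0.05 over 6. Too few members passed the filter to score mast cell (2), B cell (3), T and NK cell (3), erythroid (1) and eosinophil (2) markers. Over all 30 scored lists, 4 stood apart upward and 6 downward for rATB, 1 and 1 for buffer, and 4 and 1 for the control.

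The comparison of buffer with the untreated control asks what the vehicle and a separate culture did. By the fixed rule 0 genes were higher and 7 lower in the buffer library, and with scaling by library totals, added after seeing the data, 1 was higher and 6 lower. Nos2 was at 0.586 units with buffer against 7.48 in the control, where 10 reads stood against 133, and the control level was 12.8 times the buffer level (interval 6.74 to 27.3). Egln3, an oxygen sensor gene induced by hypoxia, was at 18.2 units against 59.6 (ratio 3.29, interval 2.89 to 3.74). Stc2 and Ngp were at 5.74 and 4.98 units against 13.4 and 11.2, and the control level of Selenbp1 was 2.21 times the buffer level (interval 1.89 to 2.60). The others were Selenbp2 and 4930583H14Rik, chosen after their values were seen, at 0.820 and 0.995 units against 2.76 and 3.99. Nos2, Egln3, Selenbp2 and 4930583H14Rik were by the fixed rule also lower with buffer than with rATB. Stc2 and Selenbp1 were lower with buffer by less, with rATB levels 1.86 (interval 1.44 to 2.41) and 1.73 (interval 1.46 to 2.06) times the buffer levels. The largest rise was that of Il12b, at 17.4 units against 8.66 (ratio 2.01, interval 1.65 to 2.46), followed by Cep78, Cst7, Ndrg4 and Cdkn2b with ratios of 1.99, 1.78, 1.68 and 1.67. Of the 30 scored lists, 11 lay outside the middle 95% of random lists for buffer minus control (3 above and 8 below). The counts were 12 for rATB minus buffer and 14 for rATB minus control. The 2 libraries without the protein thus also differed in many lists. Each pair has its own random range, which is narrower for buffer minus control, where differences spread less. These counts therefore do not compare the sizes of the differences. Glycolysis and hypoxia genes had a median of -0.48 for buffer minus control over 23 members, below the middle 95% of random lists, and the rATB library lay between the others, 0.34 above buffer and -0.15 from the control. Vegfa of that list was at 351 units with buffer against 491 in the control and 518 with rATB, and Hif1a at 662 against 634 and 752. Ngp was the gene in which the control library stood above both others, at 11.2 units against 4.98 and 2.92.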

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

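Scaling by library totals was chosen after seeing the data, and all other alternatives were planned. The 148 genes that stood apart for rATB were kept in full with a pseudocount of 0.1 (239 genes), without a filter (153) and with the highest row for each symbol (148). Median-of-ratios scaling gave 154 genes, of which 145 were shared, upper-quartile scaling 156 with 147 shared, and library totals 152 with 143 shared. A filter at 5 units left 112, all among the 148. No named gene past the fixed rule against both other libraries changed direction under any setting that gave it a value. A pseudocount of 0.1 took 6 further named genes past that rule, and each of the 3 other scalings took Tnfrsf9 past it.

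A pseudocount of 0.1 gave 183 genes higher and 175 lower for rATB against buffer, 188 and 203 against the control, and 20 and 37 for buffer against the control. The rATB library was then lower than both others in 124 genes. The buffer library was higher than both others in 4 genes and lower in 14, and the control library in 3 and 8. By its construction a smaller pseudocount lets genes of few reads pass the size rule. With a filter at 5 units, 75 genes were higher for rATB against buffer and 78 against the control, and 2 were lower in buffer than in both others, since fewer genes were tested. Without a filter 1 gene was higher in buffer than in the control and 1 than in both others. Median-of-ratios and upper-quartile scaling left 0 genes higher in the control than in both others. Library totals left 0 there, with 1 gene lower in the control than in both others and 1 higher in buffer than in the control.

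Lists are given by the smaller of the rATB medians against buffer and control. At a filter of 5 units the cytokine list moved to 0.077, the plasmacytoid list to -0.025 and the metalloprotease list to 0.054, and none of these stood apart. The inflammasome list, at -0.21, did. Without a filter the plasmacytoid list was at -0.052. The metalloprotease list also failed to stand apart with upper-quartile scaling (0.11), library totals (0.094) and unmatched random lists (0.068). Without members shared between lists it was at 0.061, the inhibitory list at 0.00 and the inflammasome list at -0.21, which stood apart. The cause of these changes was not tested beyond what each setting removes. The other lists kept their side under every setting that gave them a value, and the stromal list had too few members at a filter of 5 units. A second unit per library was planned as an alternative and not run, since the table gives only 1. No paired analysis was possible because each group has 1 library. Depth limits genes near 1 unit, which rest on about 16 to 18 reads per library.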

Other observations

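The tests of single cultures, of cell types, of a Toll-like receptor ligand and of the scaling of the buffer column were chosen after the results were seen, and those of GC content and transcript length before. In the next 2 paragraphs Tfrc, Hmox1, Arg1, Retnla and Mgl2 were named by the rule fixed before, and the other genes there were chosen after their values were seen, as were Trem2, Bnip3, Ero1l and Slc2a1 further below.

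Among single genes, the transferrin receptor gene Tfrc was at 41.7 units with rATB against 198 with buffer. Fth1, the ferritin heavy chain that stores iron, stood at 24970.3 units against 16881, a ratio to buffer of 1.48 (interval 1.47 to 1.49). Fth1 has many processed copies in the genome, and its level is uncertain for that reason. Hmox1, which frees iron from heme, was at 399 units against 236. The iron exporter gene Slc40a1 was lower, at 3.43 units against 8.08, while the ferritin light chain gene Ftl1 stood at 1575 against 1571. The metallothionein genes Mt1 and Mt2, which bind zinc, were at 166 and 60.4 units against 98.7 and 22.1.

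Arg1 and the arginine transporter gene Slc7a2 were higher with rATB, at 2029 and 344 units against 626 and 132 with buffer, and so was Spp1, which encodes osteopontin, at 2943 against 1366. Retnla, Mgl2 and Igf1 were lower, at 136, 98.5 and 57.5 units against 377, 278 and 130.0. Within the uptake list the Fc receptor genes Fcgr4, Fcgr2b and Fcgr3 were higher, at 46.5, 529 and 894 units against 15.8, 297 and 569 with buffer. Fcgr1 lay between the other libraries, at 99.1 units against 87.4 with buffer and 119.6 in the control, and 18 of the 27 members of that list were lower than in both other libraries. Saa3 was at 540.2 units against 146, Tnfsf14 at 84.7 against 24.1, and Icos at 16.8 against 5.45.

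The first pattern weighed is the set of 148 genes in which the rATB library stood apart from both others, and the treatment is the biological explanation the design gives. Bias by GC content or transcript length is argued against as the whole cause, since 138 of the 148 still stood apart after the trends with both were removed. A difference between single cultures that has nothing to do with the treatment may also give such genes. The buffer and control libraries stood apart in at most 4 genes, yet a single pair of cultures does not show how far cultures spread. With 1 library per group the treatment and anything else that set that culture apart cannot be told apart.

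The second pattern is the lower class II genes beside the higher maturation genes with rATB. For class II, buffer minus control had a median of -0.30, below the middle 95% of random lists. Part of the gap to the control was thus there without the protein, and a difference between single cultures stays open. A smaller share of dendritic cells would lower their other markers alike. The class II median lay below the lower quartile of the conventional dendritic cell markers against both libraries, by -0.17 at the least. Those markers did not move alike, since 6 of 15 were higher and 7 lower than in both other libraries. The comparison therefore cannot exclude a changed share of dendritic cells. Fewer macrophages in the treated culture stay open. By over 2 standard deviations of the buffer minus control differences at their level, 7 of 20 macrophage markers were lower than in both others. By the same measure 1 (Trem2) was higher. The list as a whole had medians of -0.01 against buffer and -0.27 against the control, and buffer minus control was already at -0.20. A smaller share of macrophages was not tested apart for the lower uptake receptors and stays open for them too. A Toll-like receptor ligand in the protein preparation could raise maturation genes. The NF-kB target list had medians of -0.052 against buffer and -0.14 against the control. The type I interferon-stimulated list had medians of 0.08 and -0.04. All 4 medians lay inside the middle 95% of random lists, which neither shows nor excludes such a ligand after 48 h. A hypothesis that rATB itself sets off a maturation with less class II transcription, with Ciita at 106 units against 171 with buffer, was not tested apart from these.

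The third pattern is the low level of glycolysis and hypoxia genes in the buffer library, at a median of -0.48 from the control. The scaling of the buffer column is argued against, since a column factor moves all genes nearly alike and the median over all genes was -0.05. Under the 3 other scalings the list median stayed at -0.39 or lower. That check could hardly end otherwise, since those scalings put the median over all genes between 0.004 and 0.028. Bias by GC content or transcript length is argued against too, with a median of -0.37 after its removal. Bnip3, Ero1l and Slc2a1 were at 31.1, 101 and 179 units with buffer against 59.6, 160.4 and 273 in the control. A candidate explanation is a difference in oxygen supply or cell density between the culture wells, which was not tested, nor was an effect of the buffer. A ratio of rATB to buffer for such genes, Egln3 among them, therefore rests partly on the low buffer value.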
